A study of Mus musculus with 5 samples.

How the data were processed

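RNA was sequenced from microglia, the resident macrophages of the brain, of C57Bl/6 mice aged 4 weeks. Per the labels' protocols, the mice received 2 mg tamoxifen on postnatal days 14 and 16. Brains were digested with papain, cells positive for eYFP (a yellow fluorescent reporter) were sorted, and libraries were made with the NEBNext Ultra II kit from 10 ng of RNA of integrity number 7 or above. The labels give 2 groups. In the control group, with 2 libraries, the mice carried 1 floxed and 1 wild-type allele of A20 and a tamoxifen-inducible Cre recombinase in the Cx3cr1 locus, and the labels call these microglia partially deficient. In the A20 deletion group, with 3 libraries, the microglia are described as fully deficient. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

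The deposited values are counts of reads per Ensembl gene in 1 table, not normalized. STAR 2.4.0j, featureCounts (version not given), DESeq2 1.22.1 and genome build GRCm38 are named per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies are therefore uncertain, among them the H2-Q genes, Ifit3 and Ifit3b, the Bcl2a1 genes, the Gbp, Ly6, ribosomal protein, ferritin and globin genes, and a gene and its antisense partner cannot be told apart. The table held 41388 genes, of which 40254 matched a GENCODE M21 symbol by Ensembl identifier and 1134 did not. The genes without a symbol held between 0.0557% and 0.069% of the counts of a library and stayed in the tests, because each has an Ensembl identifier.

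Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12240, and libraries were scaled by the trimmed mean of M values (TMM). Both groups were compared with edgeR's quasi-likelihood test (glmQLFit, glmQLFTest, two-sided) with no covariate. Benjamini-Hochberg adjustment was used with a threshold of 0.05. Levels are CPM computed on the scaled library total, and ± is the SD between libraries. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic and is approximate. For genes with no counts in the controls the fold is a lower bound, set against 3 counts over both control libraries together. For 1 to 3 control counts the ratio of pooled counts is given with its exact 95% interval. These bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

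Gene lists, tests and the rule for named genes were fixed before the data were examined. The 33 lists cover inflammatory, interferon, antigen presentation, microglial state and metabolic genes, library quality, and markers of other cells the sort could hold. Of 826 list entries, 2 were found under an older symbol and 6 were not found in the table. Each list with at least 3 tested members was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 33 lists. Camera compares a list with all other genes. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, in 1 direction. The genes named are Tnfaip3, the 8 largest rises and the 8 largest falls among called genes with an average log2 CPM of at least 3 and no overlap between the groups (predicted genes and clones left out), and per list up to 3 members with the smallest p, plus the member with the highest CPM in lists of other cells. The first 2 parts drew on 263 called genes that met these conditions, 203 of them higher. Some genes that the rule names are not reported here. A gene outside this rule is marked as chosen after its values were seen.

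The procedure was tested on simulated data, 10 sets of counts drawn from these libraries with 200 genes changed in each. Over a median of 11913 genes tested it recovered 1.23% of genes changed 1.5-fold, 11.2% of those changed 2-fold and 71.6% of those changed 4-fold. Of 604 calls 64 were false (10.6%). Camera called the list that had been raised 1.5-fold in 10 of the 10 sets, and 0 of 200 unchanged lists. The simulated genes varied independently and the lists held random genes. These sets therefore do not show how camera with the preset correlation performs on lists of correlated genes.

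Alternatives planned beforehand were other scalings (DESeq2's size factors, upper quartile, library size alone), no filter and a stricter filter (at least 5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, a robust fit, an adjusted p under 0.01, a minimum log2 fold of 1, the replicate number as a block, leaving out each library in turn and, for the lists, leaving out genes that are in more than 1 list. After the data were seen, 4 were added. The first omitted A20 deletion replicates 2 and 3, the libraries with over 3% mitochondrial counts. The others added a term for that share, added a term for sex-linked transcripts, or removed each library's trend of log2 CPM on exonic length (loess, span 0.5). Figures were drawn with matplotlib 3.10.9.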

Results

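Bulk RNA sequencing was used to compare sorted brain microglia labelled as fully deficient for A20 with microglia labelled as partially deficient. A20, encoded by Tnfaip3, is a ubiquitin-editing enzyme that restrains NF-kB signalling. The comparison asks how the transcriptome of microglia in young mice differs between these genotypes. The control libraries held 13946211 and 15275199 counts, and the A20 deletion libraries 11902432, 12883827 and 9726334. Between 15653 and 17501 genes were detected per library. A count of 3 corresponded to between 0.192 and 0.306 CPM. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom between 15.5 and 145.

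The A20 deletion libraries were not alike in structure. Mitochondrially encoded transcripts took 1.19% and 0.852% of counts in the controls and 0.847% in A20 deletion replicate 1, but 4.63% and 3.56% in replicates 2 and 3. Genes longer than the median of the tested genes held 48% and 46.9% of the tested genes' counts in the controls, 44.9% in A20 deletion replicate 1, and 37.8% and 38.5% in replicates 2 and 3. On the first principal component (58.5% of variance) control replicates 1 and 2 lay at -56 and -41, A20 deletion replicate 1 at -17.6, and replicates 2 and 3 at 50.5 and 64. On the second (22.9%) A20 deletion replicate 1 stood apart at -57.6, and the other libraries lay between 5.55 and 32.8. Xist was counted 780 times in control replicate 1 and 616 times in A20 deletion replicate 1, which held 12 and 7 counts of Y-linked genes. The other libraries held 0 counts of Xist and 1256 to 2171 counts of Y-linked genes. The 2 controls were thus not repeats of 1 sample, nor was A20 deletion replicate 1 a repeat of replicate 2 or 3. The spread within each group includes this difference.

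Tnfaip3 (ENSMUSG00000019850, GRCm38 chromosome 10, 19000910 to 19015657) stood at 454.1 and 94.75 CPM in the control libraries and at 294.6, 276.9 and 347.5 CPM in the libraries labelled A20 deletion. The group means were 274.4 ± 254.1 CPM (SD, n = 2) and 306.4 ± 36.75 CPM (SD, n = 3). The log2 fold change was 0.16 (SE 0.55, edgeR adjusted p = 0.881), so no difference was detected. Counts over all exons do not check the deletion, because the labels do not say which exons are removed and the control cells carry 1 deletable allele themselves. The value rested on the controls: it was 1.65 without control replicate 1 (adjusted p = 0.108) and -0.62 without control replicate 2 (adjusted p = 0.464), and adjusted p ranged from 0.108 to 0.973 over all alternatives.

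**Figure D1:**
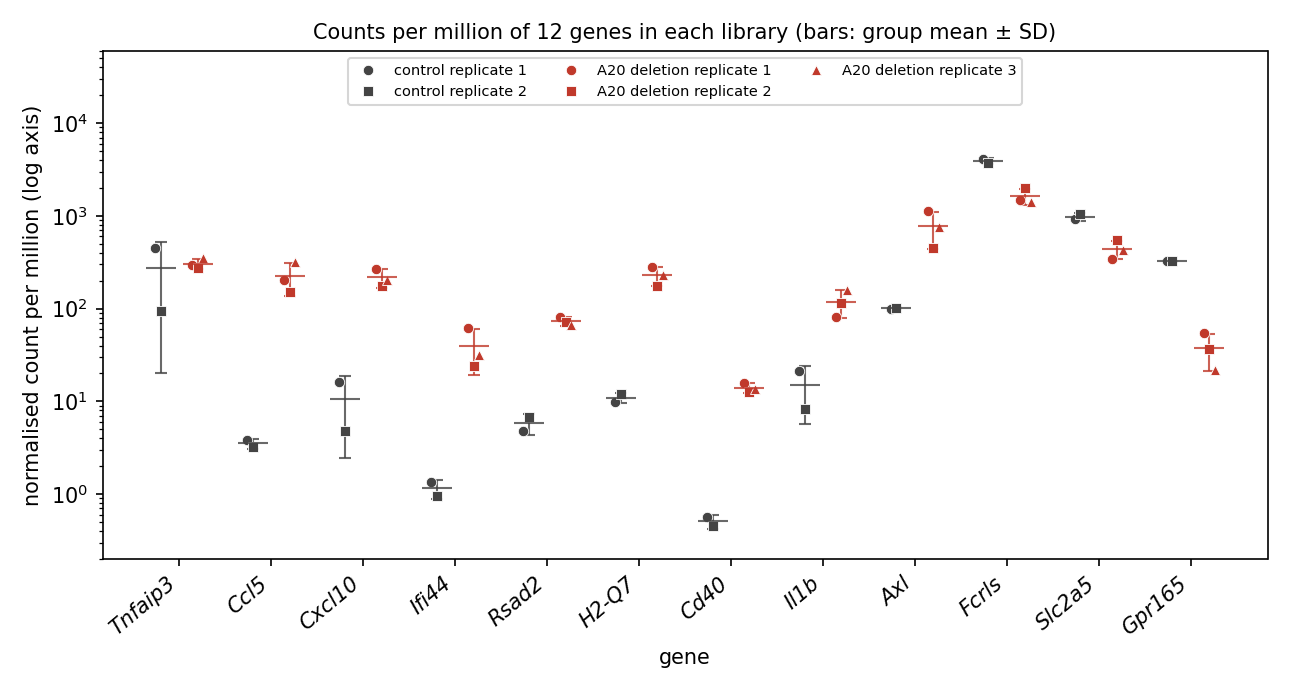
Normalised counts (CPM, log axis) of 12 genes in each library, with horizontal bars at the group mean and error bars of 1 SD (control n = 2, A20 deletion n = 3). For the 11 genes other than Tnfaip3 the groups do not overlap, as for Ccl5 at 3.841 and 3.207 CPM in the controls against 150.2 to 318 CPM, while the A20 deletion values of Tnfaip3 lie between those of the controls.

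The A20 deletion libraries held more transcripts of the chemokine and interferon-stimulated genes named here. Markers of T and NK cells and most of the tested monocyte markers were higher in them too, as given below. Ccl5, a chemokine that attracts T cells, was 63.4-fold higher (log2 fold change 5.99, SE 0.42, n = 2 and 3), and Cxcl9, a ligand of CXCR3, was 53.4-fold higher (log2 5.74, SE 0.75). Cxcl9 stood at 70.61 CPM in A20 deletion replicate 1 and at 22.4 and 22.51 CPM in replicates 2 and 3 (log2 from 4.94 to 6.63 over the alternatives). The interferon-induced genes Ifi44 and Oas3 rose 33.9-fold and 29.6-fold, the early activation antigen Cd69 rose 29-fold and the costimulatory receptor Cd40 27.2-fold. Oas3 was highest in A20 deletion replicate 1 (130.3 CPM, against 32.78 and 41.05 in replicates 2 and 3). Its log2 fold change ranged from 3.98 to 5.83 over the alternatives. The lymphoid chemokine Cxcl13 had 2 counts in both controls together against 2190 in the A20 deletion libraries, a ratio of 953 (95% interval 263 to 7870). Most of these came from A20 deletion replicate 1 (1625 counts, against 233 and 332 in replicates 2 and 3), so the size of the ratio leans on that library. Ly6i, of the Ly6 surface protein family, had 0 counts in the controls and 466 in the A20 deletion libraries, at least 135-fold higher.

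Fewer genes fell. The orphan receptor Gpr165 was 8.68-fold lower (325.6 ± 4.268 against 37.43 ± 16.06 CPM, log2 fold change -3.12, SE 0.34, n = 2 and 3). The matrix metalloproteinases Mmp28 and Mmp15 were 6.78-fold and 4.43-fold lower, the semaphorin Sema6d 6.25-fold and the circadian-output transcription factor Hlf 4.61-fold lower. Klhdc8b, Myo18b and the Notch-regulated Nrarp were 4.25-fold, 3.74-fold and 3.6-fold lower. These 16 genes had edgeR adjusted p between 0.00224 (Cd40) and 0.0302 (Sema6d). In each the 3 A20 deletion libraries lay on 1 side of both controls, which the naming rule required.

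In all, 317 of 12240 genes passed the threshold, 255 higher (80.4%) and 62 lower, and 2575 had an unadjusted p under 0.05. The groups did not overlap in any of the 317. Among all genes tested 4923 (40.2%) did not overlap, where chance gives 20%. After removal of each library's length trend 165 genes were higher (65.5%) and 87 lower, and the median log2 fold change of all genes was -0.12 against 0.05. The number rested on single libraries: 18 genes passed without control replicate 1, 0 without control replicate 2 (1323 at an unadjusted p under 0.05), 3923 without A20 deletion replicate 1 (1902 higher), 178 without A20 deletion replicate 2 and 90 without A20 deletion replicate 3. Without control replicate 2 no gene named here passed. All 317 kept their direction in every one of these fits, but this adds no support. Where the groups do not overlap, leaving out a library can hardly turn a direction. DESeq2 called 1110 genes, including the 317. With A20 deletion replicates 2 and 3 both omitted 394 genes passed, 244 of them among the 317, and with a term for their mitochondrial share 442 passed, 273 of them shared. The fit that omits both has 1 A20 deletion library, assumed to vary like the controls, so its counts rest on the spread between 2 libraries. Without A20 deletion replicate 1 the labelled groups coincide with the mitochondrial and short-gene shares of replicates 2 and 3. Counts from that fit, here and for each list below, cannot be told apart from that structure.

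The type I interferon response was the list with the most calls. Of its 38 tested genes 30 rose and 0 fell, and 35 rose adjusted over the list alone, with a median log2 fold change of 2.99. The antiviral enzyme Rsad2 went from 5.783 ± 1.438 to 73.3 ± 7.83 CPM (12.6-fold, log2 3.66, SE 0.24), Ifit3 rose 12.1-fold and Ifi27l2a 9.07-fold, each with an edgeR adjusted p of 0.00223. Irf7, the transcription factor that amplifies interferon production, rose 14.8-fold and was chosen after its values were seen. For the list camera gave an adjusted p of 4.77e-28, and adjusted p = 0.301 with an estimated correlation. The list median was 3.53 above the control mean in A20 deletion replicate 1 and 2.35 and 2.65 in replicates 2 and 3. Members higher numbered 3 without control replicate 1 and 0 without control replicate 2, and 36 with A20 deletion replicates 2 and 3 omitted.

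Guanylate-binding protein and interferon-gamma response genes had 8 of 19 members higher and 0 lower (13 higher adjusted over the list alone), with a median log2 fold change of 1.63. The chemokine Cxcl10 rose 20.6-fold, from 16.29 and 4.811 CPM to between 175.4 and 269.7 CPM (log2 4.36, SE 0.54, adjusted p = 0.013 by edgeR). The GTPases Iigp1 and Gbp2 rose 13.2-fold and 6.51-fold. The camera adjusted p was 1.14e-09, and adjusted p = 0.302 with an estimated correlation. Members higher were 1 without control replicate 1, 0 without control replicate 2 and 4 without A20 deletion replicate 3, and 13 without A20 deletion replicate 1 or with replicates 2 and 3 omitted.

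Of 27 cytokines and chemokines 12 rose and 0 fell, and 20 rose and 1 fell adjusted over the list alone, with a median log2 fold change of 2.03. Ccl12 went from 24.75 ± 3.334 to 215.4 ± 31.23 CPM (8.71-fold, log2 3.12, SE 0.21, edgeR adjusted p = 0.00224), and Cxcl16 rose 4.05-fold. The cytokine Il1b rose 7.98-fold, from 14.88 ± 9.244 to 118.5 ± 39.84 CPM. Tnf, chosen after its values were seen, stood at 148.7 and 18.86 CPM in the controls and at 229, 122.9 and 113.4 CPM in the A20 deletion libraries and did not pass (adjusted p = 0.503). For the list as a whole the camera adjusted p was 3.2e-13, and adjusted p = 0.214 with an estimated correlation. Members higher were 3 without control replicate 1, 0 without control replicate 2, 6 with limma-voom and 19 without A20 deletion replicate 1 (with 1 lower).

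In both classes some antigen presentation genes rose and others did not pass. For MHC class I 15 of 23 genes were higher and 0 lower (18 higher adjusted over the list alone), with a median log2 fold change of 1.37. The non-classical H2-Q7 rose 20.9-fold (log2 4.39, SE 0.28), H2-Q5 11.2-fold and H2-Q4 6.83-fold, although reads may be divided unevenly among these near-identical genes. The light chain B2m, chosen after its values were seen, rose 2.87-fold from 2540 ± 112.8 to 7287 ± 436.8 CPM. For MHC class II 5 of 15 genes were higher and 0 lower (8 higher adjusted over the list alone), with a median of 0.74. These were Cd40, H2-Ab1 (3.33-fold) and Cd74 (3-fold), and, outside the naming rule, the lysosomal Ifi30 (2.39-fold) and Ctss (1.67-fold). Camera gave adjusted p of 3.32e-14 and 5.71e-05, and for both lists adjusted p = 0.214 with an estimated correlation. Class I members higher were 2 and class II members 1 without control replicate 1, both were 0 without control replicate 2, and class II members were 2 without A20 deletion replicate 3, 10 without A20 deletion replicate 1 and 2 after the length correction.

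NF-kB targets and feedback genes were higher for 7 of 31 members and lower for 0 (11 higher adjusted over the list alone), with a median log2 fold change of 0.60. Besides Cd40, Bcl3, a nuclear IkB protein, rose 4.37-fold (3.844 ± 0.9009 to 16.82 ± 3.13 CPM, log2 2.13, SE 0.29) and the survival gene Bcl2a1a 3.21-fold. Relb, the transcription factor of the non-canonical pathway, rose 2.39-fold and the ubiquitin ligase Birc3 2.09-fold, both chosen after their values were seen. Camera gave an adjusted p of 7.26e-06, and adjusted p = 0.302 with an estimated correlation. The list median lay 0.924, 0.695 and 0.595 above the control mean in A20 deletion replicates 1 to 3, and 0.138 above it in control replicate 1. Summed over 33 members, control replicate 1 lay within the A20 deletion range. The sums were 4550 and 2380 CPM in control replicates 1 and 2 and 5140, 4490 and 4250 CPM in A20 deletion replicates 1 to 3. Members higher were 1 without control replicate 1, 0 without control replicate 2, 4 without A20 deletion replicate 2, 1 without A20 deletion replicate 3 and 12 without A20 deletion replicate 1 (with 2 lower).

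Among 15 inflammasome and pyroptosis genes only Il1b passed (2 higher adjusted over the list alone, median log2 fold change 0.27). The caspase gene Casp4 was at 9.687 ± 0.1828 and 42.28 ± 19.71 CPM (adjusted p = 0.0506 by edgeR) and the adaptor Pycard at 91.91 ± 3.612 and 163.1 ± 45.19 CPM (adjusted p = 0.155). The list gave a camera adjusted p of 0.102 and a fry adjusted p of 0.0471 (range over the alternatives 0.00228 to 0.353). Of 30 pattern recognition receptors and proximal signalling genes 1 fell, the flagellin receptor Tlr5 (2.89-fold lower, log2 -1.53, SE 0.20), and 0 rose (1 higher and 1 lower adjusted over the list alone, median 0.12, camera adjusted p = 0.73). Tlr2 stood at 296.7 ± 3.466 and 526.8 ± 61.48 CPM (adjusted p = 0.0543) and Fpr2 at 0.1032 ± 0.05524 and 2.502 ± 1.852 CPM (adjusted p = 0.0977). Il1b and Tlr5 did not pass without either control replicate or without A20 deletion replicate 3, nor Il1b without A20 deletion replicate 2. The first list, without A20 deletion replicate 1, had 5 higher and 3 lower and the second 1 higher and 7 lower. With A20 deletion replicates 2 and 3 omitted both lists passed by camera (adjusted p = 0.0046 and 0.002).

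Homeostatic microglia genes were lower as a list by camera (adjusted p = 5.06e-06, but adjusted p = 0.301 with an estimated correlation), and few passed singly. Of 33 members 2 fell and 0 rose, and 10 fell adjusted over the list alone, with a median log2 fold change of -0.42. Fcrls went from 3888 ± 288.3 to 1633 ± 326.3 CPM (2.38-fold lower, log2 -1.25, SE 0.19, edgeR adjusted p = 0.0217) and the fructose transporter Slc2a5 was 2.23-fold lower. Tgfbr1 stood at 4402 ± 890.5 and 2195 ± 402.2 CPM and did not pass (adjusted p = 0.0529). P2ry12, Cx3cr1 and Tmem119, chosen after their values were seen, had log2 fold changes of -0.58, -0.51 and -0.27 and did not pass. Members lower were 0 without either control replicate or without A20 deletion replicate 3, 18 without A20 deletion replicate 1 (with 2 higher), and 5 with A20 deletion replicates 2 and 3 omitted.

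Disease-associated microglia genes, a set described in neurodegeneration, were higher for 9 of 29 members and lower for 1 (16 higher and 3 lower adjusted over the list alone), with a median log2 fold change of 0.57. The receptor tyrosine kinase Axl rose 7.69-fold (101 ± 2.357 to 776.1 ± 332.6 CPM, log2 2.94, SE 0.38), the surface glycoprotein Cd52 3.78-fold and the ferritin heavy chain Fth1 2.29-fold. The member that fell was the pyrophosphate transporter Ank (2.32-fold lower), chosen after its values were seen. Apoe was at 1298 and 706.3 CPM in the controls and at 3184, 2430 and 5758 CPM in the A20 deletion libraries (adjusted p = 0.0735 by edgeR). Camera gave an adjusted p of 7.26e-05, and adjusted p = 0.301 with an estimated correlation. Members higher were 0 without either control replicate, 2 without A20 deletion replicate 3 and 16 without A20 deletion replicate 1 (with 3 lower).

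Of 25 complement and phagocytic receptor genes 7 rose and 1 fell (14 higher and 2 lower adjusted over the list alone, median log2 fold change 0.54). The receptors Cd300lf and Fcgr4 rose 14.7-fold and 4.03-fold. The complement components C3 and C4b, chosen after their values were seen, rose 16.6-fold and 13.2-fold, and the scavenger receptor Stab1, likewise chosen, was 2.24-fold lower. Of 32 lysosome genes 5 rose and 0 fell (8 higher adjusted over the list alone, median 0.31). They were Ctsz (1.97-fold), Ctsh (1.92-fold), Npc2 (1.85-fold) and, outside the naming rule, Ctss (1.67-fold) and Cd63 (1.92-fold). Camera gave adjusted p of 0.00187 and 0.0117, with adjusted p = 0.302 and 0.49 with an estimated correlation. Both counts of higher members were 0 without either control replicate, and without A20 deletion replicate 3 they were 3 and 0, without replicate 2 they were 6 and 0, and without replicate 1 they were 12 and 12, with 6 and 4 lower. The lysosome list did not pass without control replicate 1 (adjusted p = 0.211) or A20 deletion replicate 1 (0.147), without a filter (0.0588), or with members of 1 list only (0.114).

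**Figure D2:**
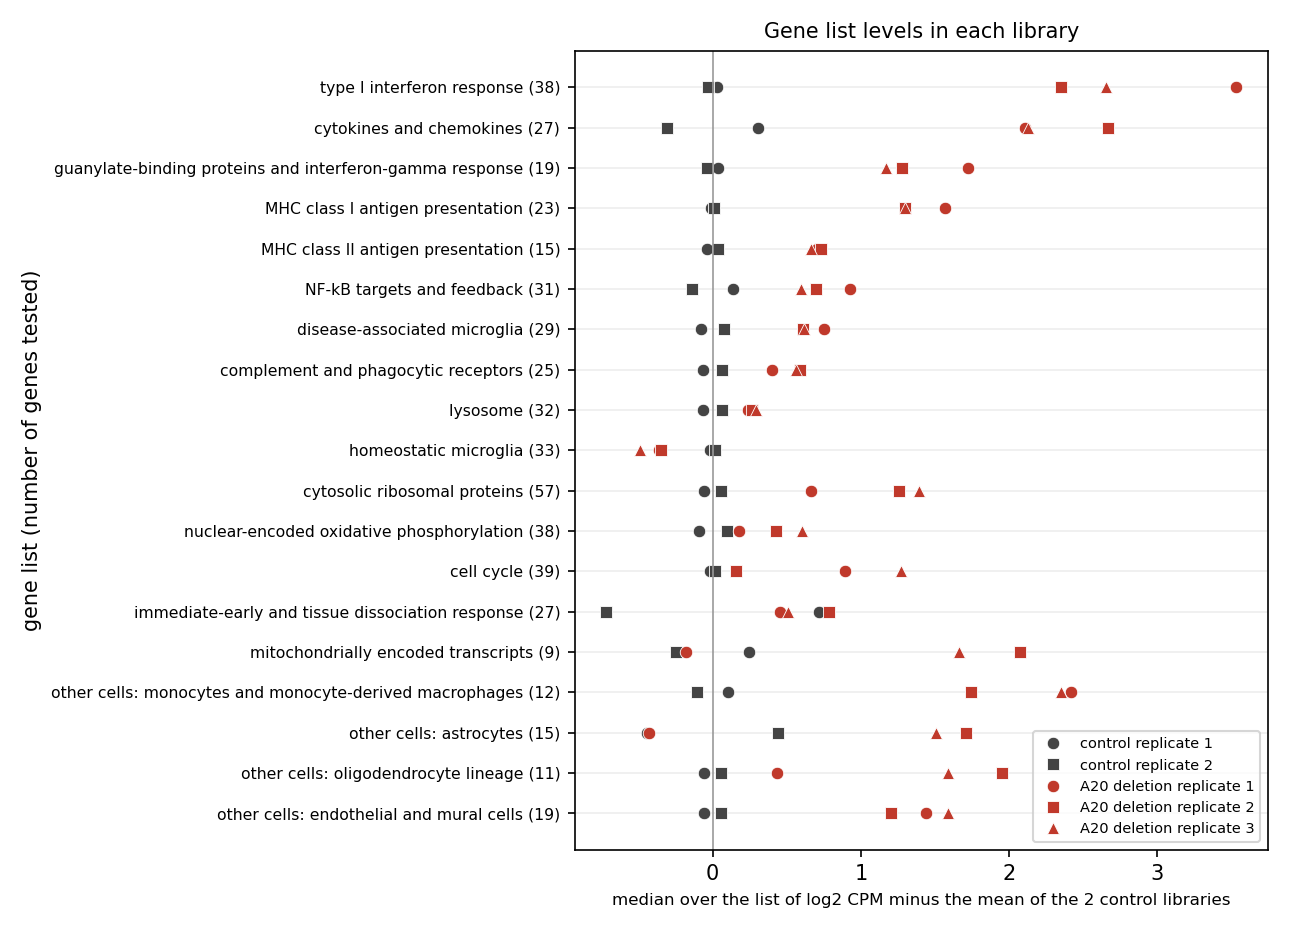
Median over each gene list of a gene's log2 CPM minus the mean of the 2 control libraries (x axis), for 19 lists (y axis, number of tested genes in brackets), with 1 point per library. The type I interferon list lies at 3.53, 2.35 and 2.65 in the 3 A20 deletion libraries, whereas the astrocyte list lies at -0.43 in A20 deletion replicate 1 and at 1.71 and 1.51 in replicates 2 and 3.

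Cytosolic ribosomal protein genes were higher together by camera (adjusted p = 6.31e-20, but adjusted p = 0.331 with an estimated correlation). Of 57 members 10 rose and 0 fell, and 48 rose adjusted over the list alone, with a median log2 fold change of 1.15. Rpl32 went from 237.9 ± 10.39 to 643.8 ± 175.1 CPM (2.71-fold, log2 1.44, SE 0.25), Rpl19 rose 2.69-fold and Rps25 2.34-fold, all subject to reads from processed pseudogenes. The list median lay 0.66 above the control mean in A20 deletion replicate 1 and 1.26 and 1.39 above it in replicates 2 and 3, the libraries with more counts in short genes. Members higher were 0 without either control replicate and without A20 deletion replicate 2 or 3, 50 without A20 deletion replicate 1, 1 after the length correction and 6 with A20 deletion replicates 2 and 3 omitted.

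Nuclear-encoded oxidative phosphorylation genes had 0 of 38 members past the test with edgeR (0 adjusted over the list alone, 16 higher at an unadjusted p under 0.05), 7 with DESeq2 and 0 with limma-voom. Their median log2 fold change was 0.41, and Cox8a (74.57 ± 10.49 and 150.5 ± 35.99 CPM) had an adjusted p of 0.0815. The 9 mitochondrially encoded transcripts had 0 past the test with edgeR (0 adjusted over the list alone, 5 unadjusted), 1 with DESeq2 and 0 with limma-voom. Their median was 1.43, made up of -0.18 in A20 deletion replicate 1 against 2.07 and 1.66 in replicates 2 and 3, and mt-Co1 stood at 2862, 2098, 2296, 13640 and 10510 CPM in the order control replicates 1 and 2, A20 deletion replicates 1 to 3. Camera gave adjusted p of 5.71e-05 and 0.0279, with adjusted p = 0.567 and 0.605 with an estimated correlation. Without A20 deletion replicate 1, 20 of the 38 and 9 of the 9 were higher, and after the length correction the oxidative phosphorylation list did not pass (adjusted p = 0.589, over a range from 8.97e-07 to 0.589). The direction of the mitochondrial list turned with A20 deletion replicates 2 and 3 omitted (adjusted p = 0.173), over a range of adjusted p from 4.56e-05 to 0.605.

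Of 39 cell cycle genes 1 rose, the thymidine kinase Tk1 (6.43-fold, 1.485 ± 0.01303 to 9.611 ± 3.923 CPM), and 0 fell (2 higher adjusted over the list alone). The list median was 0.92, with 0.89, 0.16 and 1.27 in A20 deletion replicates 1, 2 and 3. Tk1 did not pass without either control replicate or without A20 deletion replicate 2 or 3, and without replicate 1 the list had 6 higher and 1 lower. The camera adjusted p was 1.13e-05, with adjusted p = 0.474 with an estimated correlation. Immediate-early and tissue dissociation genes had 0 of 27 past the test with edgeR (0 adjusted over the list alone, 4 unadjusted), 2 with DESeq2 and 0 with limma-voom. Their median was 0.33, with a difference of -1.43 between control replicates 2 and 1, and Egr2 (48.89 ± 3.189 and 113.4 ± 53.63 CPM) had an adjusted p of 0.159. Camera gave 0.0238, adjusted p = 0.605 with an estimated correlation. Members higher were 4 without A20 deletion replicate 1 and 3 without control replicate 1, and the direction turned without control replicate 2 (adjusted p = 0.157, over a range from 3.4e-11 to 0.605).

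Among 24 glycolysis and hypoxia genes 2 rose and 0 fell (3 higher adjusted over the list alone, median log2 fold change 0.26, camera adjusted p = 0.0317, adjusted p = 0.583 with an estimated correlation). Acod1, which makes itaconate and is induced by inflammatory signals, had 0 counts in the controls and 143 in the A20 deletion libraries, at least 41.5-fold higher, and the glycolytic Pfkp rose 4.24-fold. Neither passed without either control replicate or without A20 deletion replicate 3, and Pfkp did not pass without A20 deletion replicate 2. The list had 4 higher and 3 lower without A20 deletion replicate 1 and did not pass there (adjusted p = 0.372) or without control replicate 1 or 2 (0.175 and 0.0612), without a filter (0.0836), or with members of 1 list only (0.0737). Of 16 synapse and neurite growth factor genes Mmp14 rose (2.39-fold, adjusted p = 0.0498 by edgeR) and 0 fell (1 higher adjusted over the list alone, median 0.34, camera adjusted p = 0.6). Mmp14 did not pass without either control replicate or without A20 deletion replicate 2 or 3, and without replicate 1 the list had 3 higher and 4 lower. Hbegf stood at 11.08 ± 1.334 and 4.689 ± 1.452 CPM (adjusted p = 0.112).

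The other 3 lists fixed for microglia had 0 members past the edgeR test over all genes, and 9, 7 and 6 of them in turn had an unadjusted p under 0.05. For 24 TGF-beta and microglia identity regulators 2 rose and 4 fell adjusted over the list alone, DESeq2 called 2 higher and 5 lower and limma-voom 0, and the median and mean log2 fold changes differed in sign (-0.07 and 0.04, camera adjusted p = 0.152). Smad3 stood at 230.8 ± 1.365 and 122.1 ± 26.19 CPM (adjusted p = 0.071). For 28 apoptosis and necroptosis genes 0 passed adjusted over the list alone, DESeq2 called 1 higher and 1 lower and limma-voom 0. Their median was 0.03 while camera pointed down and fry up (camera adjusted p = 0.73), and Pmaip1 was at 12.29 ± 4.046 and 27.26 ± 2.383 CPM (adjusted p = 0.0705). For 25 cholesterol and lipid handling genes 1 rose and 1 fell adjusted over the list alone, DESeq2 called 2 higher and 1 lower and limma-voom 0. Their median was 0.04 while camera pointed down and fry up (camera adjusted p = 0.73), and Scd2 was at 233.7 ± 11.31 and 147 ± 10.79 CPM (adjusted p = 0.0769). With A20 deletion replicate 1 left out the 3 lists had 2 higher and 10 lower, 2 higher and 6 lower, and 3 higher and 7 lower, in the same order.

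Markers of other blood and border cells were measured in the same libraries. Of 12 monocyte markers 3 rose and 0 fell (6 higher adjusted over the list alone, median log2 fold change 2.31): Ms4a4c 10.1-fold, the integrin Itgal 10.2-fold and Plac8 8.81-fold. The monocyte chemokine receptor Ccr2, chosen after its values were seen, had 162 and 128 counts in the controls and 94, 66 and 54 in the A20 deletion libraries. These counts are not scaled, and the A20 deletion libraries held fewer counts in all, so they overstate the fall. Scaling to the library totals narrows the fall but does not remove it. Of the 12 markers 11 had a positive log2 fold change and 1, Ccr2, a negative one. Summed over 31 T and NK cell markers the libraries held 2.49 and 2.76 CPM in the controls and 17.3, 11.1 and 10.5 CPM in the A20 deletion libraries. Of the 3 tested singly (Cd4, Thy1 and Lck) 0 passed over all genes with edgeR, 3 rose adjusted over the list alone and had an unadjusted p under 0.05, 1 passed with DESeq2 and 0 with limma-voom. Of 3 B cell markers Cd22, an inhibitory lectin also made by microglia, rose 5.68-fold and the others did not pass (1 higher adjusted over the list alone, median 0.42). Camera gave adjusted p of 7.32e-05, 0.00455 and 0.0272 for monocytes, T and NK cells and B cells, and for each adjusted p = 0.301 with an estimated correlation. Monocyte markers higher were 1 and 0 without control replicates 1 and 2, and Cd22 passed in neither of these fits. Without A20 deletion replicate 1, 5 monocyte markers were higher and 1 lower, and 2 T and NK cell markers were higher. By camera the B cell list did not pass in that fit (adjusted p = 0.0667), with the replicate block (0.0551) or after the length correction (0.334). In all it passed in 15 of 21 alternatives.

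For 7 neutrophil, 16 border-associated macrophage, 10 dendritic cell and 4 erythroid markers 0 passed over all genes with edgeR (1, 5, 4 and 0 at an unadjusted p under 0.05), and camera gave adjusted p of 0.73, 0.0865, 0.282 and 0.96. DESeq2 called 1 neutrophil marker, 2 border-associated macrophage markers and 1 dendritic cell marker higher and 1 dendritic cell marker lower, and limma-voom 0. Adjusted over the list alone, 1 neutrophil marker rose, 1 dendritic cell marker rose and 1 fell, and 0 of the others passed. Csf3r was at 231 ± 16.47 and 347.7 ± 15.04 CPM, Mrc1 at 63.85 ± 30.45 and 58.57 ± 6.241 CPM, Fscn1 at 1254 ± 20.31 and 832 ± 43.14 CPM, and Hbb-bs at 0.07113 and 13.6 CPM in the controls and 4.332, 11.08 and 0 CPM in the A20 deletion libraries. The list medians were -0.88, 0.30, 0.41 and -0.29, and the neutrophil median lay below 0 while camera pointed up. Relative to the control mean the neutrophil median was 2.28 and -2.28 in control replicates 1 and 2. It was 1.35, -1.20 and -0.23 in A20 deletion replicates 1 to 3. S100a8, chosen after its values were seen, had 66 and 0 counts in the controls and 30, 6 and 7 in the A20 deletion libraries. Neutrophil markers thus differed between the 2 controls, although Csf3r was at 219.4 and 242.7 CPM in them. Without A20 deletion replicate 1, 1 neutrophil marker, 3 border-associated macrophage markers and 2 dendritic cell markers were higher and 3 dendritic cell markers lower.

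Markers of astrocytes, oligodendrocytes, neurons and endothelial cells were higher as lists by camera (adjusted p of 0.00864, 0.000407, 0.0103 and 0.00453), but not with an estimated correlation (adjusted p = 0.605, 0.301, 0.321 and 0.301). Of 15 astrocyte markers Aldh1l1 rose (5.97-fold, 1.973 ± 0.476 to 11.88 ± 5.295 CPM) and 0 fell (2 higher adjusted over the list alone, median log2 fold change 1.09). Of 11 oligodendrocyte lineage, 8 neuronal and 19 endothelial and mural markers 0 passed with edgeR (8, 1 and 10 at an unadjusted p under 0.05, 6, 0 and 0 higher adjusted over the list alone, medians 1.60, 0.99 and 1.30), DESeq2 called 2, 0 and 3 higher and 1 endothelial marker lower, and limma-voom 0. Cnp stood at 98.36 ± 3.597 and 131.1 ± 1.833 CPM, and Camk2a at 10.51 ± 3.344 and 15.46 ± 0.3685 CPM. The astrocyte median was -0.43 in A20 deletion replicate 1 and 1.71 and 1.51 in replicates 2 and 3, the oligodendrocyte median 0.43, 1.95 and 1.59, the neuronal median 0.48, 1.32 and 1.12, and the endothelial median 1.44, 1.20 and 1.59. Aldh1l1 did not pass without any 1 of the controls or of A20 deletion replicates 2 and 3. Without A20 deletion replicate 1, 11 astrocyte, 7 oligodendrocyte, 1 neuronal and 3 endothelial markers were higher and 1 endothelial marker lower, while with replicates 2 and 3 omitted 4 endothelial markers were higher. In that last fit the oligodendrocyte and neuronal lists did not pass (adjusted p = 0.203 and 0.492), nor did the neuronal list without A20 deletion replicate 1 or 2 (0.0656 and 0.219) or the endothelial list with the stricter filter (0.612). The direction of the astrocyte list turned there (adjusted p = 0.43, over a range from 4.56e-05 to 0.605).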

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

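The alternatives chosen after the data were seen were omitting A20 deletion replicates 2 and 3, the mitochondrial-share term, the sex-linked transcript term and the length correction. All 317 called genes kept their direction under each alternative, 302 of 302 where the stricter filter tested fewer. Their groups do not overlap, so for the fits that leave out libraries this was all but fixed in advance. Without a filter 1701 genes changed (1048 higher, 653 lower), with DESeq2 1110 (744 higher, 366 lower), with limma-voom 211 (166 higher), with the sex-linked transcript term 824 (563 higher, 261 lower), after the length correction 165 were higher, and at an adjusted p under 0.01 58 changed (56 higher, 2 lower). Leaving out 1 library gave 0 to 3923 changed genes, 0 to 1902 higher and 0 to 2021 lower. With 1 control left, that library is assumed to vary like the A20 deletion libraries, and A20 deletion replicate 1 like the controls where it stands alone. The cause of these differences was not tested, except that fewer samples enter the fits that leave out libraries and fewer genes pass a lower threshold. With an estimated correlation 0 of 33 lists passed, against 23 with the preset one and 19 with fry (fry does not compare a list with other genes).

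The camera direction reversed for the immediate-early list without control replicate 2 (adjusted p = 0.157, and 3.4e-11 to 0.157 over the fits that leave out 1 library), and for the mitochondrially encoded and astrocyte lists with A20 deletion replicates 2 and 3 omitted (0.173 and 0.43) and with the mitochondrial-share term (0.165 and 0.422). In these last fits the libraries that carried the rise no longer contribute to it. Of the other list tests 601 stayed on the same side of the threshold, 65 lost it and 14 gained it. Counts of list members past the threshold stayed within 1.5 times in 211 cases and moved further in 294. Tnfaip3 passed under no alternative. Of the named genes' tests 1764 stayed, 214 lost the threshold, 169 gained it and 0 reversed among called genes.

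The replicate number was tried as a block for the shared numbers 1 and 2, although the labels do not say what a number shares. Same-numbered libraries deviated together with a correlation of 0.26 and 0.167, over 2 pairs. Number 3 occurs only in the A20 deletion group, so the contrast with the block rests on these pairs. Both libraries of number 1 held Xist counts (780 and 616) and both of number 2 held Y-linked counts (2171 and 2150). The block therefore cannot be told apart from sex-linked composition in these pairs. The replicate block gave 260 changed genes (228 higher, 32 lower), 219 of them among the 317, and 21 lists. Of the lysosome genes 0 were higher with the block, against 5 without it.

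Only 10 splits of the 5 libraries into 2 and 3 exist, too few for a share under 0.05. The real split gave 317 genes, and 2 of the 10 gave as many: the other set A20 deletion replicates 2 and 3 against the rest and gave 2050, which points to a structure of the samples. Depth limited genes near the floor of 0.192 to 0.306 CPM.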

Other observations

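The genes in these opening paragraphs, and the tests of the interferon genes against library structure and of Tnfaip3 in control replicate 2, were chosen after their values were seen. Ifnb1, which encodes interferon beta, had 0 counts in the controls and 100 in the A20 deletion libraries, at least 29-fold higher (adjusted p = 0.0267 by edgeR, n = 2 and 3). The receptors Slamf8 and Slamf9 rose 4.71-fold and 3.02-fold, and Cd72, an inhibitory receptor, rose 7.49-fold. The common cytokine receptor chain Il2rg went from 6.055 ± 1.396 to 48.01 ± 4.311 CPM (log2 fold change 2.99, SE 0.23). The adhesion molecule Vcam1 rose 9.97-fold and Lag3, a receptor for MHC class II, rose 1.97-fold. The T cell receptor complex genes Cd3d, Cd3e and Cd3g together had 0 counts in both controls (floors of 0.213 and 0.192 CPM) and 16, 13 and 11 counts in the A20 deletion libraries, or 1.39, 1.02 and 1.12 CPM. None of these calls passed without control replicate 2.

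The ferritin chains Fth1 and Ftl1 rose 2.29-fold and 2.05-fold, subject to reads from pseudogenes, and the ferroxidase ceruloplasmin (Cp) went from 4.864 ± 0.7419 to 56.91 ± 31.1 CPM (11.7-fold). The iron exporter ferroportin (Slc40a1) was 1.88-fold lower (252.6 ± 46.95 to 134.6 ± 6.059 CPM, adjusted p = 0.0451 by edgeR), while Hmox1 and Tfrc did not pass (adjusted p = 0.387 and 0.319). The Notch pathway genes Jag2 and Notch4 were 2.45-fold and 2.19-fold lower, and the Notch target Hes1 did not pass (log2 fold change -0.22, adjusted p = 0.832). The basement membrane genes Nid2 and Lamb2 were 2.95-fold and 2.22-fold lower. Among semaphorins Sema4b was 3.26-fold lower and Sema4a 3.84-fold higher.

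The interferon, chemokine and MHC class I genes were weighed against the structure of A20 deletion replicates 2 and 3 and against sex-linked composition. Over the 88 members of the 3 lists the median log2 fold change was 2.22, with 57 higher. It was 2.45 with the mitochondrial-share term (lower quartile 1.44, 64 higher), a fit that leans on A20 deletion replicate 1. After the length correction, a fit that uses all libraries, it was 1.99 (lower quartile 0.80, 45 higher). This argues against the length trend as the whole cause. The correction removes only the trend on exonic length, and 1 library cannot decide on the rest of that structure. Among libraries with Xist counts the median difference was 2.29 and among those with Y-linked counts 2.26, which argues against sex-linked composition. The A20 deletion named by the design stays open as a hypothesis. The rest of the structure of replicates 2 and 3 stays open too, as does any difference in day or handling that the labels do not give.

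The ribosomal protein genes were weighed against the length trend and the same structure. After the length correction the list median was 0.70 (SE over members 0.047) against 1.15 before, so the trend may account for part of the rise. Fewer members then passed singly (1 against 10). Whether the trend accounts for the whole is not decided. The correction used the length of all annotated exons of a gene together, as 2691 bases for Rps25, which can exceed the length of its transcripts. The median in A20 deletion replicate 1 was 0.66 (lower quartile 0.55, difference between the controls 0.12). In replicates 2 and 3 it was 1.26 and 1.39. With the mitochondrial-share term the list median was 0.69 (SE over members 0.037, not between libraries). That term marks only replicates 2 and 3, so the fit repeats the comparison of replicate 1 with the controls. The list was thus higher in replicate 1 too, but 1 library cannot decide whether the structure of replicates 2 and 3 is the whole cause. The length trend, the structure of those replicates, RNA quality and the A20 deletion all stay open as causes.

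Tnfaip3 was lower in control replicate 2 than in control replicate 1 by a log2 difference of -2.26. The 27 immediate-early and tissue dissociation genes had a median difference of -1.43 between the same libraries, with 22 of 27 lower, below the lowest of 10000 random lists matched on expression (-0.21). The random genes were drawn singly, so a list of genes that vary together can fall outside their range whatever the cause. The cytokine and chemokine list differed by -0.613 and the neutrophil list by -4.57 between the same libraries. A response to tissue handling that differed between the control libraries is therefore only a hypothesis. A deleted library with a wrong label was predicted to have Tnfaip3 at the level of the A20 deletion libraries. In control replicate 2 it differed from their mean by a log2 difference of -1.68 (SD over the 3 libraries 0.17). This cannot decide on a wrong label, because Tnfaip3 counts do not check the deletion. A weaker handling response could also lower them in a deleted library. The type I interferon list median differed by -0.06 between control replicates 2 and 1. It lay 3.53, 2.35 and 2.65 above the control mean in the A20 deletion libraries. On that list control replicate 2 thus resembled the other control, and which alleles it carried was not tested.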
